A study of Mus musculus with 19 samples.

How the data were processed

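Drop-seq, which counts transcripts by unique molecular identifiers (UMIs) in cells caught in droplets with barcoded beads, was run on cells of the medial amygdala of male C57BL/6J mice aged 8 or 9 weeks, and 19 libraries carry labels. Act-Seq, the dissociation used for 17 of them, is a protocol built to limit transcription during tissue dissociation, and 2 libraries came from a conventional dissociation. The Act-Seq libraries came from naive mice (6 libraries), a saline-injected control (1), mice after seizure (2), mice stressed by immobilization (4) and mice exposed to odors (4); the conventional libraries came from a saline-injected control (1) and a mouse group after seizure (1). The labels say that the odor libraries served cell typing without immediate early genes and were kept out of the immediate early gene comparison, so the odor comparison is additional. Seizure 1, immobilization 2 and 3 and odor 1 and 2 came from mice of 9 weeks, and all others, with every naive library among them, from mice of 8 weeks. No label says that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

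The authors deposited 3 tables of whole-number UMI counts per gene and cell, which the values bear out as raw counts. Per the submitters' processing notes, base calls were made with bcl2fastq 2.17.1.14 and reads were aligned with STAR 2.5.0a to mm10; the counting tool and the cell filters are not given in the sources used here. The first table holds 20679 cells, 16233 genes and 35709950 UMIs in 16 Act-Seq libraries, and no cell has fewer than 430 genes. The second holds 2444 neurons and 3343 genes, all found by name and with identical counts in the first. The third holds 8071 cells, 15299 genes and 16872067 UMIs in the 5 libraries that compare dissociations. No table holds a mitochondrially encoded gene, so the 15 genes of that list gave no result. The deposited cell names of the first 2 tables carry the library and the authors' class or neuron cluster; names in the third carry the library. Whether the counting used strand is not given in the sources used here, so overlapping genes cannot be told apart.

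Cell classes in the first table were the authors' own (astrocyte, endothelial, microglia, mural, oligodendrocyte and precursor), with the cells of the neuron table as neurons. The authors' neuron class of the first table holds 8499 cells, of which 2293 are in the neuron table; the others formed a separate class. Cells of the third table were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.8, seed 1, log2 of counts per 10000), leaving out the genes of the immediate early and neuronal activity lists. Clusters were named from markers of 18 classes fixed before the data were examined, from at least 3 detected markers of a class. Further, 3 clusters (led by Kif5a, Trbc2 and Top2a) were left unnamed after their leading genes were seen to mix classes or to be genes of cell division. In the first table, own clusters led by Rgs5 (162 cells) and Ctss (375 cells) were left unnamed in the same way; these clusters serve an alternative and the comparison of levels across tables. Scrublet, run within scanpy, called 0.469% of cells in the first table and 0.979% in the third; the first share is too low for a working caller, so no cell was removed and the removal of the 5% of cells with the highest doublet scores was tried.

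Counts were summed per library and class where a library had at least 10 cells of it, and tested with the quasi-likelihood F-test of edgeR 4.0.16 (TMM scaling, filterByExpr) in R 4.3.3, with 1 fit per class over the 4 Act-Seq groups and no covariate. P-values were adjusted by the Benjamini-Hochberg method within a class, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were the fold divided by the root of the F statistic. Levels are given in CPM, scaled to the UMIs of a library in a class, as mean ± SD over libraries. The dissociation fit had terms for seizure and method over 5 libraries, which leaves 2 residual degrees of freedom; a further fit with their interaction leaves 1. Fold changes against a group with no UMI are lower bounds against a floor of 3 counts over the group. The fits of neurons and astrocytes and the dissociation fits of microglia and astrocytes were tested on simulated counts with 200 genes changed. These came from a negative binomial model with the library sizes, the pooled profile and the gene dispersions of these libraries. They hold no other differences between libraries, so the recovery in the real data may be lower. Unchanged genes that were called ranged from 2 to 12 per fit. The other fits and the interaction were not tested in this way. In neurons, edgeR recovered 53.1%, 50.5% and 55.7% of genes changed by a log2 of 1 and 87.2%, 91.6% and 91.8% of those changed by a log2 of 2, after seizure, immobilization and odor. In astrocytes it recovered 60.2%, 68.4% and 67.3%, and 83.7%, 94.9% and 93.9%. For the dissociation fit it recovered 36.7% and 93.1% in microglia and 56.7% and 89.5% in astrocytes.

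Gene lists fixed at the same time as the markers were tested with camera of limma 3.58.1 on the edgeR fits, two-sided, with a preset correlation of 0.01 and beside it an estimated one, where at least 5 members were tested, adjusted over lists and classes of a contrast. They hold immediate early transcription factors (29 genes), neuronal activity effectors (29), glucocorticoid responsive genes (24), heat shock (16), inflammatory (22), unfolded protein and amino acid response (17), hypoxia (16), circadian (16), reactive astrocyte (18), neuropeptides (20), synaptic and excitability (23), myelin and lipid synthesis (17), blood-brain barrier (14) and mitochondrially encoded genes (15). The named genes follow a rule written at the same time: per contrast, in neurons the 8 raised and 5 lowered genes with the smallest p past the threshold, in other classes the 4 raised and 2 lowered, and for dissociation the 4 raised and 3 lowered. It also takes the 4 members of a list with the smallest p in each direction, 10 immediate early and glucocorticoid genes where their list is discussed, and in a class with no gene past the threshold the 3 with the smallest p. Some genes the rule takes were left out of the text, and 1 is not reported here and not counted among the alternatives.

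Shares of cells per class and of cells with a Fos UMI were compared between libraries by exact two-sided permutation tests; for the latter each cell was thinned to 600 UMIs, with no neuron or astrocyte left out for fewer. The alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, the replicate number as a block, age as a covariate, own clusters as classes, doublet removal, another Leiden resolution (1.6) and leaving out each library; others were added after the data were seen. Same-numbered libraries did not deviate together, so the block was not used in the fits reported here. Replicate libraries differed by more than sampling noise (chi-square per degree of freedom of 1.49 or more), so none was counted as a duplicate. This does not show that they came from separate preparations or animals. Intervals are exact binomial ones at 95% and, like the floors, cover counting error alone. Gene positions are from GENCODE vM21 on GRCm38, the assembly also called mm10.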

Results

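The Act-Seq libraries held 43 (naive 6) to 2189 cells (immobilization 1) and 116492 to 3723521 UMIs, with a median of 1222 UMIs and 772 genes per cell. Naive 5 (230 cells), naive 6 (43), immobilization 4 (182) and odor 4 (425) were the smallest. Naive 6 entered no class, and odor 4, with 5 neurons, entered the neuron comparison as no library, so neurons were compared over 5 naive, 2 seizure, 4 immobilization and 3 odor libraries. The other classes had 5, 2, 4 and 4 libraries, and mural cells 4, 2, 3 and 3. Neurons gave 23479 to 1035400 UMIs per library and astrocytes 74620 to 1286560, whereas endothelial cells reached at most 183266 and mural cells 52971. The 5 libraries that compare dissociations held 2010 (saline 7), 1777 (seizure 1), 1123 (seizure 2), 1880 (saline_conventional 1) and 1281 cells (seizure_conventional 1) and 2102364 to 4309887 UMIs. Genes tested in the first table ranged from 10520 in astrocytes and 8808 in neurons to 1020 in mural cells.

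Neurons made up 11.1% ± 4.45 of cells in naive libraries (SD, n = 6), 13.4% ± 4.91 after seizure (n = 2), 10.4% ± 3.45 after immobilization (n = 4) and 8.41% ± 5.56 after odor (n = 4). Exact permutation tests of 8 classes in 3 comparisons with naive libraries found no share past the threshold (lowest adjusted p 0.584). With 2 seizure libraries the smallest p these tests allow is 0.0357, so no single class could pass alone after adjustment over 8 classes. The precursor share after seizure was 5.61%, against 6.53% in all naive libraries. Without libraries under 300 cells the naive share was 3.11% (exact permutation p = 0.0667, the smallest allowed, adjusted p 0.533).

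The first comparison asked which cells turned on activity-dependent genes after seizure. In neurons, Fos, a transcription factor subunit induced within minutes of strong synaptic input (chromosome 12, 85473890 to 85477273, plus strand), stood at 148 ± 24.2 CPM after seizure (SD, n = 2) and at 4.50 ± 3.43 CPM in naive libraries (n = 5). This was a log2 rise of 4.73 (SE 0.42, adjusted p 2.92e-11). Its relatives Fosb and Junb rose by a log2 of 4.16 (SE 0.61) and 3.30 (SE 0.39). Egr1 and Egr4, zinc finger factors of the same kind, rose by 2.43 (SE 0.28) and 3.62 (SE 0.47). Arc, a regulator of synaptic receptor traffic (chromosome 15, 74669083 to 74672570, minus strand), rose by 3.23 (SE 0.41), from 8.43 ± 9.57 CPM to 95.2 ± 22.7 CPM. All 9 neuronal genes past the threshold rose. The other 3 were Nfkbia, an inhibitor of NF-kappaB (1.29, SE 0.28), and the neuropeptides Sst (1.27, SE 0.26) and Npy (1.63, SE 0.35).

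The 6 immediate early genes stayed past the threshold without any 1 library. Sst, Npy and Nfkbia did not. Without seizure 1 the log2 values were 0.57 for Sst (adjusted p 0.999), -0.15 for Npy (0.999) and 1.41 for Nfkbia (0.412). Without naive 1 they were 1.23 for Sst (0.0664) and 0.98 for Nfkbia (0.338), without seizure 2 the value was 1.21 for Nfkbia (0.203), and without naive 5 it was 1.61 for Npy (0.0704). Sst is among the leading genes of the authors' neuron cluster N12, and without those cells the log2 values of Sst and Npy were -0.03 and -0.28, whereas in own clusters led by Meg3 or Snhg11 they were 5.49 and 5.90 (adjusted p 2.1e-05 and 3.09e-05). With age as a covariate Sst and Npy were at 0.88 and 0.83 (adjusted p 1 for both). Nr4a1 (2.06, adjusted p 0.0744), Npas4 (2.30, 0.513), Jun (0.71, 0.999), Sgk1 (1.57, 0.808) and Fkbp5 (0.43, 0.999) did not pass in neurons. DESeq2 called 6 neuronal genes.

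Of the immediate early transcription factors, 5 of 15 tested members rose in neurons, and 10 adjusted over the list alone (median log2 1.20, camera adjusted p 2.86e-42, and 2.85e-06 with an estimated correlation). The neuronal activity effectors had 1 of 19 members past the threshold (median 0.42, adjusted p 0.0113 with an estimated correlation). The neuropeptides had 2 of 11, with 3 raised and 2 lowered adjusted over the list alone (median 0.20, camera adjusted p 0.0174, and adjusted p = 0.0517 with an estimated correlation). After thinning to 600 UMIs, 8.34% ± 0.678 of neurons held a Fos UMI after seizure (n = 2) and 0.472% ± 0.527 in naive libraries (n = 6), which the exact permutation test put at p = 0.0357, the smallest it allows (adjusted p 0.107). Unthinned, the shares were 23.6% ± 2.99 and 0.971% ± 0.934. In oligodendrocytes, taken as a background, the thinned share was 0 in both groups and the unthinned share 2.23% ± 0.912 after seizure; the median depth before thinning was 2252 and 2100 UMIs in neurons and 2118 and 2208 in oligodendrocytes of seizure 1 and 2. The inhibitory minus excitatory difference in summed immediate early CPM moved by a log2 of 0.06 between naive (n = 4) and seizure (n = 2) libraries (exact permutation p = 1). The smallest p this test allows is 0.0667, so it could not pass the threshold and does not show that both types responded alike. In both types these sums were higher in each seizure library than in any naive one (725 and 1232 against at most 514 CPM in inhibitory, 1437 and 1585 against at most 802 CPM in excitatory neurons). In separate fits of these neuron types, with 1 and 2 immediate early members tested, edgeR called 0 genes after seizure in either (unadjusted 101 and 63, DESeq2 0 and 0). Adjusted over the list alone, Egr1 rose in excitatory neurons (2.35, SE 0.74).

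**Figure D1:**
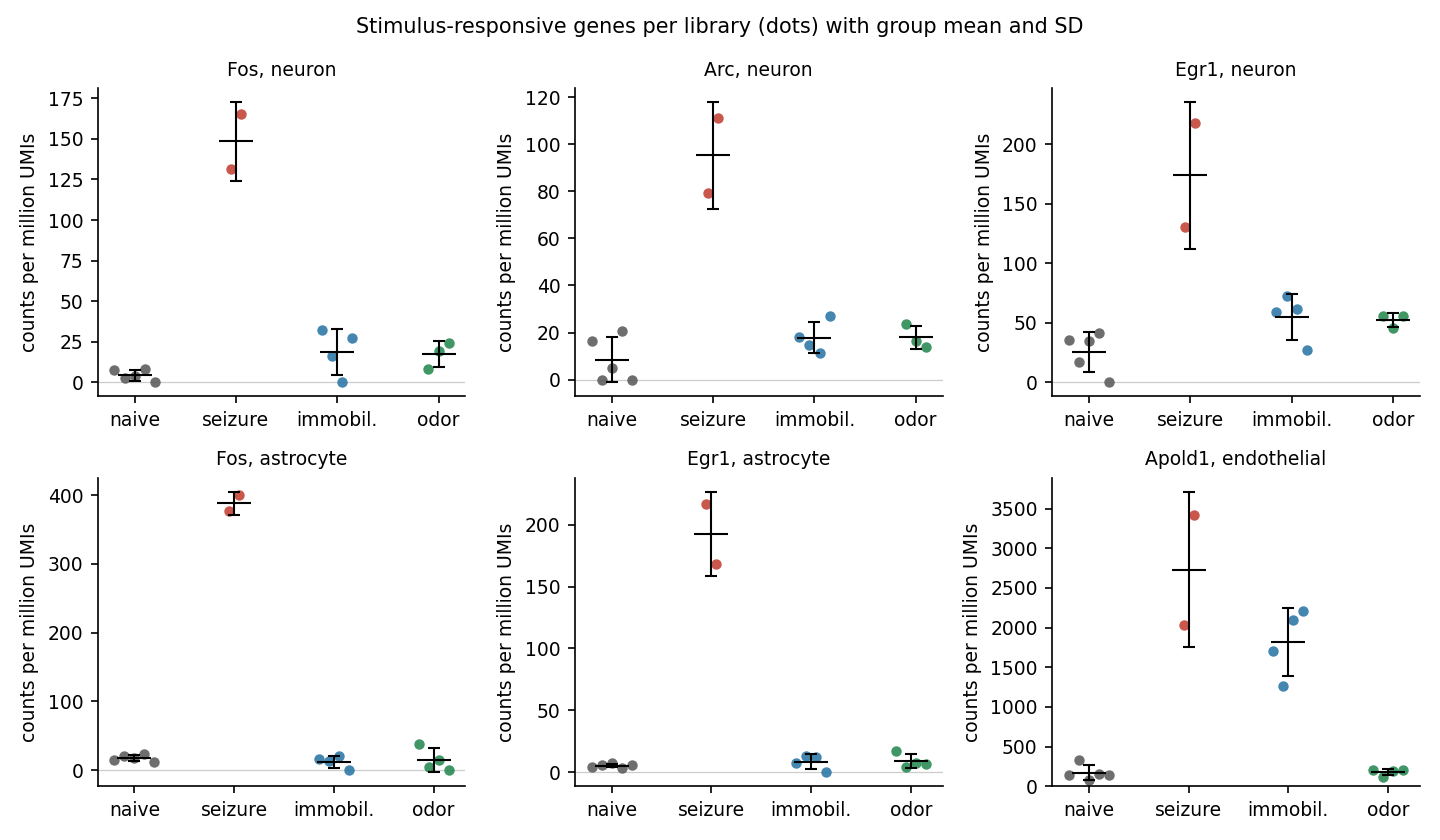
Levels of Fos, Arc and Egr1 in neurons, Fos and Egr1 in astrocytes and Apold1 in endothelial cells, in CPM of a library in that class (linear axis that includes 0), in the naive, seizure, immobilization and odor groups. Points are libraries, and bars the mean with its SD; Fos in neurons averaged 148 CPM after seizure and 4.50 CPM in naive libraries, and Apold1 averaged 2728 CPM after seizure, 1819 CPM after immobilization and 178 CPM after odor.

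In the classes of glia and vessels 125 class-gene pairs passed the threshold after seizure, 112 of them raised. In astrocytes Fos reached 388 ± 16.6 CPM (n = 2) against 17.6 ± 4.93 CPM (n = 5), a log2 rise of 4.42 (SE 0.25), and Egr1 reached 193 ± 34.0 against 5.22 ± 1.34 CPM, a rise of 5.18 (SE 0.30). Nr4a1, an orphan nuclear receptor, rose by 4.53 (SE 0.47), Junb by 3.62 (SE 0.43) and the matricellular protein gene Cyr61 by 2.48 (SE 0.22). Dio2, the deiodinase that makes active thyroid hormone, rose from 81.7 ± 22.4 to 341 ± 44.4 CPM (log2 2.02, SE 0.18). The Notch target Hes5 fell by 1.44 on the log2 scale (SE 0.18), from 843 ± 133 to 309 ± 92.3 CPM. Arl4d, a small GTPase of the ARF family, had no UMI among 3248596 in naive astrocytes and was at least 39.2-fold higher after seizure against a floor of 3 counts over the group. In all, 49 astrocyte genes changed, 40 of them raised.

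In endothelial cells Apold1, an immediate early gene of vessels (chromosome 6, 134981718 to 134986836, plus strand), rose from 170 ± 96.1 CPM (n = 5) to 2728 ± 979 CPM (n = 2), a log2 of 3.97 (SE 0.31). Nr4a1 rose by 4.57 (SE 0.54), Fosb by 5.12 (SE 0.78), Maff by 2.73 (SE 0.44) and the phosphatase gene Dusp1 by 2.51 (SE 0.34), among 25 genes past the threshold. Egr1 (2.77, SE 0.62) and Jun (1.37, SE 0.30) rose too, but not without seizure 2 (1.63 and 0.74, adjusted p 1 for both), without naive 1 (2.32, 0.0815, and 1.33, 0.0538) or without naive 3 (2.38, 0.0668, and 1.20, 0.0668). Mural cells raised 7 genes, led by Errfi1, an inhibitor of epidermal growth factor receptor signalling (1466 ± 243 against 116 ± 52.9 CPM, n = 4; log2 3.76, SE 0.46), and the metallothioneins Mt2 (3.23, SE 0.52) and Mt1 (2.88, SE 0.48). In oligodendrocyte precursors Egr1 rose by 5.65 (SE 0.43), to 827 ± 383 CPM from 14.3 ± 17.8, and Nr4a1 by 2.68 (SE 0.29), among 6 genes. Microglia changed 28 genes, led by other genes: Tsc22d3 (glucocorticoid-induced leucine zipper) rose by 2.72 (SE 0.25), Ddit4, an inhibitor of mTORC1, by 3.18 (SE 0.32), Nfkbia by 2.31 (SE 0.22) and Sgk1, a kinase induced by glucocorticoids, by 1.52 (SE 0.20). Oligodendrocytes raised 10 genes, among them Polr3e, a subunit of RNA polymerase III (2.15, SE 0.22), and Nfkbia (1.91, SE 0.28). Without seizure 2 the 125 pairs became 64.

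By list, immediate early members rose in 6 of 15 in astrocytes (12 raised and 1 lowered adjusted over the list alone, median 1.57), 8 of 19 in endothelial cells (14 and 1, median 1.37), 1 of 7 in mural cells (6 adjusted over the list alone, median 2.55), and 2 of 5 in oligodendrocyte precursors (3, median 0.71). They rose in 1 of 10 in microglia (4 and 1, median 0.55) and 0 of 6 in oligodendrocytes (3, median 0.62; edgeR called 10 oligodendrocyte genes in all, DESeq2 5, and 376 were under an unadjusted 0.05). Camera called the list upward in each of these classes, with an estimated correlation too. Activity effectors rose in 6 of 18 members in astrocytes, led by Arl4d and Dusp1, and 2 of 11 in endothelial cells. Of the glucocorticoid responsive genes, 7 of 19 rose in astrocytes (median 0.82), 6 of 17 in oligodendrocytes (0.95), and 5 of 13 in microglia (0.57). So did 4 of 7 in mural cells (1.93), 3 of 15 in endothelial cells (0.77), 1 of 15 in neurons (0.57) and 1 of 10 in precursors (0.56), all called with an estimated correlation. The reference here was naive and not saline-injected mice. In mean log2 of CPM plus 10, this list stood at 6.08 in naive, 6.41 in saline and 6.70 in seizure Act-Seq astrocytes. In microglia these values were 5.46, 5.86 and 6.07, so part of the rise may be present without seizure, which 1 saline library cannot settle. Inflammatory genes had 1 of 8 members raised in microglia (median 0.50, adjusted p 0.00208 with an estimated correlation). Neuropeptides in astrocytes had 0 of 8 past the threshold, 4 adjusted over the list alone (adjusted p = 0.0523 with an estimated correlation). Myelin genes in oligodendrocytes and in precursors (median -0.47) were called with the preset correlation (adjusted p = 0.383 and 0.143 with an estimated correlation). In astrocytes 29.3% ± 4.54 of cells held a Fos UMI after seizure, and 15.02% ± 2.26 after thinning, against 2.29% ± 1.29 and 0.507% ± 0.527 in naive libraries (exact permutation p = 0.0357 for both, the smallest allowed).

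After immobilization, the stress comparison, 5 genes rose in neurons and 2 fell. Nfkbia, raised after seizure too, rose from 37.6 ± 25.5 CPM (n = 5) to 163 ± 41.7 CPM (n = 4; chromosome 12, 55489410 to 55492647, minus strand), a log2 of 2.01 (SE 0.24, adjusted p 3.67e-07). Tsc22d3 (X chromosome, 140539528 to 140600659, minus strand) rose from 123 ± 61.0 to 352 ± 143 CPM (1.57, SE 0.23). Dio2 rose from 35.7 ± 24.1 to 134 ± 55.9 CPM (1.86, SE 0.24), and Cdkn1a, which encodes a cell cycle inhibitor, by 2.35 (SE 0.38). Sgk1 rose by 2.03 (SE 0.42) and Hes5 fell by 0.96 (SE 0.20), both calls that were lost without single libraries. Without immobilization 1 the values of Sgk1 and Hes5 were 2.01 (adjusted p 0.264) and -0.93 (0.383), without immobilization 2 they were 2.07 (0.167) and -0.88 (0.644), and without naive 3 they were 1.77 (0.165) and -0.86 (0.133). Sgk1 was also lost without immobilization 3 (1.97, 0.0648), and Hes5 without naive 1 (-0.86, 0.14) or immobilization 4 (-0.95, 0.0534). Avp, the vasopressin gene, had no UMI among 1875634 in the immobilization neurons. This puts the naive group at least 2058-fold higher against a floor of 3 counts over the group, but naive 4 alone stood at 25439 CPM and the other 4 naive libraries at 0 to 2979 CPM. The neuron table also holds clusters led by glial genes: N16 (268 cells) is led by Dio2 and N14 (203 cells) has Nfkbia and Mal among its leading genes. N13 (244 cells) has Agt and Gjb6 among its leading genes, and N15 (271 cells) F3 and Htra1. Separate fits of inhibitory and excitatory clusters held none of these cells. There edgeR called 1 gene after immobilization, Nfkbia in inhibitory neurons (3.65, SE 0.70, adjusted p 0.00416), which DESeq2 did not call. For the other genes a change in glial RNA of these cells stays open. DESeq2 called 4 of the genes tested in neurons, against 7 by edgeR.

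None of the 15 immediate early members tested in neurons passed after immobilization (unadjusted 394 of all 8808 genes; 3 adjusted over the list alone; camera adjusted p 0.0906). Fos stood at 18.9 ± 14.2 CPM (log2 1.87, SE 0.53, adjusted p 0.331), Egr1 at 55.0 ± 19.5 CPM (1.02, 0.326), and Fosb (2.21, 0.487), Junb (1.05, 0.962) and Arc (0.70, 1) also did not pass. The thinned share of neurons with a Fos UMI was 0.465% ± 0.547 (n = 4; exact permutation p = 1), while the unthinned share was 4.14% ± 3.21 (exact permutation p = 0.0476, adjusted p 0.0714). The direct comparison of seizure with immobilization found 7 neuronal genes, all higher after seizure: Fos (2.86, SE 0.36), Arc (2.54, SE 0.41), Junb (2.25, SE 0.38), Egr4 (2.32, SE 0.44), Egr1 (1.41, SE 0.27), Npas4 (4.42, SE 0.91) and Sst (1.57, SE 0.29). Of these, Fos and Arc stayed past the threshold without any 1 library, while Junb did not without immobilization 2 (1.91, adjusted p 0.0661) nor Egr1 without seizure 2 (1.05, 0.613) or immobilization 1 (1.37, 0.0941). Sst was lost without seizure 1 (0.86, 1), immobilization 1 (1.41, 0.128) or immobilization 2 (1.47, 0.0758). Egr4 was lost without seizure 2 (2.01, 0.136), immobilization 1 (2.42, 0.0793) or immobilization 2 (2.23, 0.0969), and Npas4 without seizure 1 (4.56, 0.128), seizure 2 (4.29, 0.0618), immobilization 3 (4.24, 0.0541) or immobilization 4 (4.40, 0.0512). Counts were 3 without immobilization 1 or without immobilization 2. Npas4 stood at 0.64 ± 1.29 CPM after immobilization (n = 4), so the size of its fold is uncertain. Immediate early members were higher after seizure in 5 of 15 in neurons and 9 of 15 in astrocytes, where Fos differed by 4.66 (SE 0.27) and Egr1 by 4.14 (SE 0.28), and in precursors Egr1 differed by 7.04 (SE 0.51). In endothelial cells 0 of 19 differed (3 adjusted over the list alone; adjusted p = 0.278 with an estimated correlation).

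Outside neurons, 391 class-gene pairs passed after immobilization, 281 of them raised. Astrocytes changed 159 genes: Tsc22d3 rose to 1314 ± 218 CPM (n = 4) from 320 ± 148 CPM (n = 5; log2 2.02, SE 0.18). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose to 57.6 ± 17.7 from 4.22 ± 3.44 CPM (3.61, SE 0.38), Cdkn1a by 3.16 (SE 0.29), Dio2 by 1.88 (SE 0.16) and the lysophospholipid transporter gene Mfsd2a by 1.73 (SE 0.20). Arl4d was at least 54.2-fold higher than the naive floor. Hes5 fell by 1.04 (SE 0.14) and Sox2, a factor of glial and stem cells, by 0.80 (SE 0.12). Endothelial cells changed 70 genes, 64 of them raised. Apold1 reached 1819 ± 427 CPM (3.40, SE 0.28), and Maff (3.41, SE 0.38), Nr4a1 (3.57, SE 0.54), Fosl2 (2.64, SE 0.56), Crem (2.26, SE 0.35) and Tmcc3 (3.25, SE 0.29) rose. So did Slc2a1, the glucose transporter of the blood-brain barrier (1.26, SE 0.25). Microglia changed 95 genes, with Ddit4 at 788 ± 180 against 42.0 ± 42.0 CPM (3.91, SE 0.27), Tsc22d3 up by 3.10 (SE 0.21) and Fkbp5 by 2.42 (SE 0.24), and the chemokine gene Ccl4 lower by a log2 of -5.21 (SE 1.00). Ccl4 stood at 0.85 ± 1.70 CPM after immobilization (n = 4), so the size of its fold is uncertain. Oligodendrocytes changed 67 genes, led by Cdkn1a (201 ± 93.4 against 5.97 ± 9.41 CPM; 5.08, SE 0.39), with Sgk1 at 2510 ± 436 against 449 ± 655 CPM (2.37, SE 0.36). This fold depends on naive 2, which stood at 1619 CPM against 111 to 203 in the other naive libraries, and was 3.95 without it. In mural cells and precursors edgeR called 0 genes (unadjusted 38 and 201, DESeq2 0 and 0); the smallest p in precursors was that of Sgk1 (1.23, adjusted p 0.0973). Without immobilization 2 or immobilization 3 the 391 pairs became 248.

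Of the glucocorticoid responsive genes, more passed after immobilization than of any other list tested. They rose in 15 of 19 in astrocytes (18 adjusted over the list alone, median 1.10), 12 of 17 in oligodendrocytes (16, median 1.31), 7 of 15 in endothelial cells (11, median 1.09), 5 of 13 in microglia (7, median 0.51) and 4 of 15 in neurons (11, median 0.69). In mural cells 0 of 7 passed (3, median 1.01) and in precursors 0 of 10 (5, median 0.78; edgeR called 0 genes in these classes, unadjusted 38 and 201, DESeq2 0 and 0). Camera called the list in all 7 classes with an estimated correlation (highest adjusted p 0.0209). Immediate early members rose in 6 of 19 in endothelial cells (10 adjusted over the list alone, median 1.139, adjusted p 0.0106 with an estimated correlation). They were called downward in microglia (median -0.32, 2 of 10 lowered, among them Jun at -1.09; adjusted p = 0.127 with an estimated correlation). Without immobilization 1 or immobilization 3 the call of Jun was lost (-1.01, 0.103, and -0.99, 0.0913). Activity effectors rose in 7 of 18 in astrocytes (9 raised and 1 lowered adjusted over the list alone) and 2 of 11 in endothelial cells. Blood-brain barrier genes were called in neurons (0 of 5 past the threshold, 1 adjusted over the list alone, median 0.36, adjusted p 0.0299 with an estimated correlation) and in astrocytes (1 of 6, Mfsd2a; adjusted p = 0.178 with an estimated correlation). Calls with the preset correlation alone were circadian genes in microglia and oligodendrocytes (adjusted p = 0.291 and 0.285 with an estimated correlation), and heat shock genes downward in oligodendrocytes (median -0.30, adjusted p = 0.522 with an estimated correlation). So were neuropeptides in astrocytes (adjusted p = 0.315 with an estimated correlation) and synaptic genes downward in neurons (median -0.08, adjusted p = 0.384). Hypoxia (lowest adjusted p 0.101), unfolded protein (0.0803) and reactive astrocyte genes (0.193) gave no call in this comparison.

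**Figure D2:**
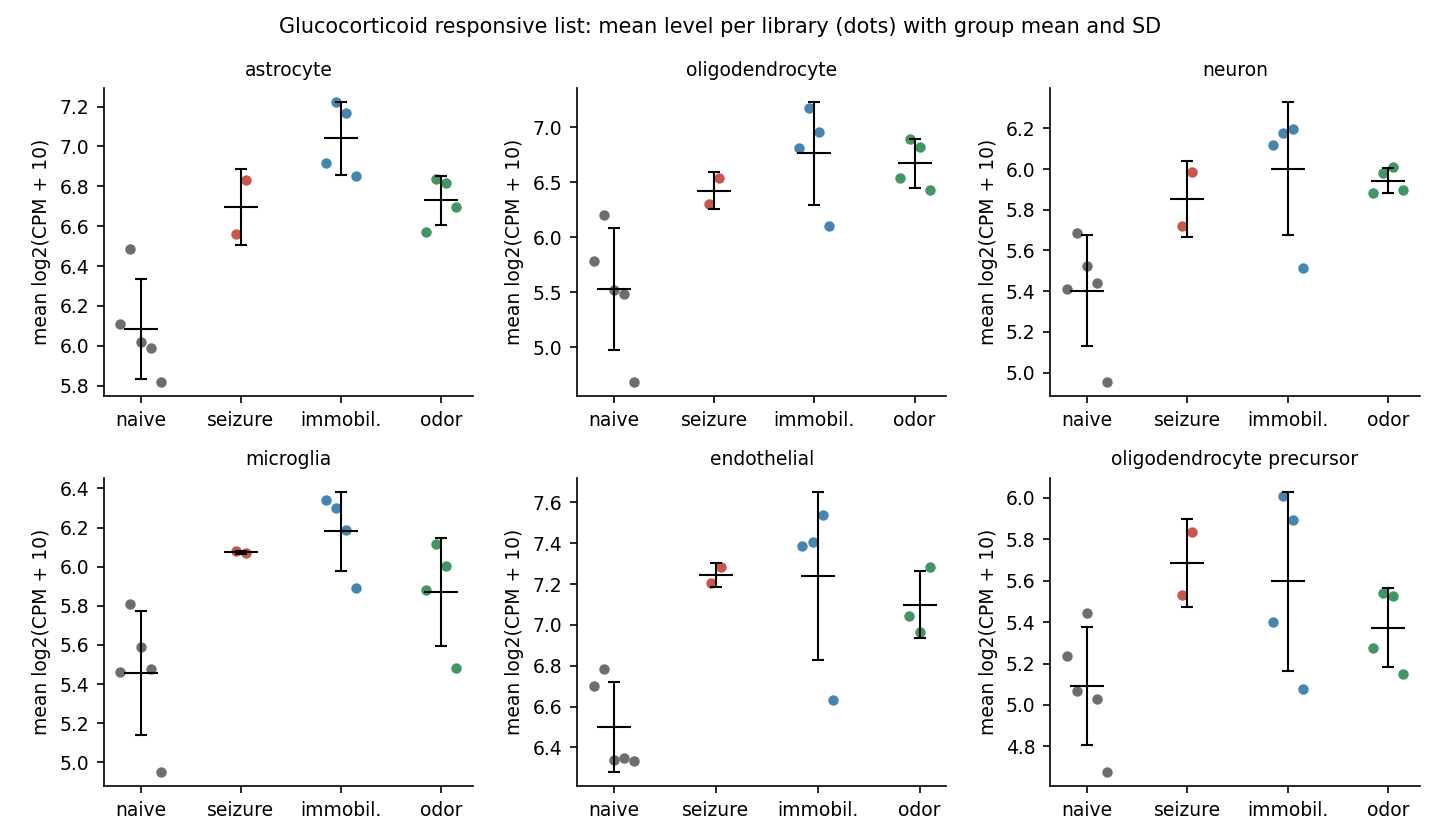
Mean log2 of CPM plus 10 over the glucocorticoid responsive genes, per naive, seizure, immobilization and odor library (points) with group means (bars), in 6 classes (the axis does not start at 0). The classes were named here from fixed markers in both tables, so that values of the saline and conventional libraries, which are not drawn, can be compared. In astrocytes the means were 6.08 in naive, 6.73 in odor and 7.04 in immobilization libraries, with the saline Act-Seq library at 6.41 and the naive libraries from 5.82 to 6.49.

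Odor exposure, which the study left out of its immediate early gene comparison, is given here as an additional comparison. In neurons Tsc22d3 rose from 123 ± 61.0 CPM (n = 5) to 403 ± 36.8 CPM (n = 3), a log2 of 1.64 (SE 0.23), the 1 gene raised. Among the 10 lowered genes the long noncoding RNA Meg3 (chromosome 12, 109541001 to 109571726, plus strand) stood at 658 ± 410 against 4478 ± 3235 CPM (-2.59, SE 0.41). Snhg11 stood at 417 ± 228 against 2579 ± 2452 CPM (-2.24, SE 0.39) and Miat at a log2 of -2.71 (SE 0.53), beside Sfrs18 (-1.27, SE 0.21) and Avp (-9.24, SE 1.68). The fall of Avp rests on naive 4 (25439 CPM) and naive 2 (2979 CPM), since the other naive libraries had 0 to 7.59 CPM and the odor libraries 8.40 to 13.1 CPM. Without odor 3 none of the 10 passed, and 1 gene remained in all (Meg3 -2.15, adjusted p 0.0829; Snhg11 -1.85, 0.238; Sfrs18 -1.10, 0.109; Avp -9.17, 0.238; Miat -2.31, 0.301). Miat was also lost without naive 1 (-1.25, 0.612), naive 5 (-2.73, 0.0519) or odor 2 (-2.50, 0.051), and Avp without odor 1 (-9.12, 0.13). Neuronal counts were 5 without naive 1, 20 without naive 2, 28 without naive 3, 19 without naive 4, 7 without naive 5, 5 without odor 1 and 7 without odor 2. Meg3, Snhg11, Miat and Sfrs18 lead the authors' cluster N12, which took 7.80% ± 7.57 of neurons in naive (n = 5) and 2.77% of those in odor libraries (exact permutation p = 0.339), and 2 genes passed without its cells. DESeq2 called 1 neuronal gene. Of 15 immediate early members, 0 passed (4 raised and 2 lowered adjusted over the list alone, median 0.10, adjusted p 0.264; DESeq2 called 1 neuronal gene in all), with Fos at 1.65 (adjusted p 0.407), Egr1 at 0.78 (0.523) and Arc at 0.90 (0.822). The thinned Fos share was 1.01% ± 0.910 (n = 4, exact permutation p = 0.243). It includes odor 4 with 5 neurons, weighted like the other libraries.

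Outside neurons 115 pairs passed after odor, 91 of them raised. In astrocytes (69 genes) Tsc22d3 rose to 984 ± 147 CPM (n = 4; log2 1.59, SE 0.18), Fkbp5 by 2.92 (SE 0.41), Hr, a nuclear receptor corepressor, by 2.69 (SE 0.33) and Cdkn1a by 2.05 (SE 0.34). Fabp7, a brain fatty acid binding protein, fell by 1.53 (SE 0.26) and the phosphate transporter gene Slc20a1 by 0.86 (SE 0.14). Oligodendrocytes (39 genes) raised Cdkn1a by 4.01 (SE 0.43), Plin4, a lipid droplet protein, by 2.60 (SE 0.39) and Sgk1 by 2.16 (SE 0.36; 3.74 without naive 2), to 2154 ± 433 CPM. Microglia (6 genes) raised Ddit4 by 2.80 (SE 0.29), Tsc22d3 by 1.88 (SE 0.23) and Fkbp5 by 1.76 (SE 0.25). In precursors 1 gene rose, Ccdc163 (4.12, SE 0.83, at 272 ± 518 CPM, n = 4). Its SD was close to the largest that 4 libraries with this mean allow, so 1 odor library carried most of the rise. The call was lost without naive 1, naive 2 or naive 5 (4.32, 4.18 and 4.01, adjusted p 0.0792, 0.213 and 0.0888). In endothelial and mural cells edgeR called 0 genes (unadjusted 238 and 89, DESeq2 3 and 1). Apold1 stood at 178 ± 42.2 CPM after odor, and a direct comparison added after the data were seen put immobilization above odor by a log2 of 3.46 (SE 0.32). Without odor 3 the 115 pairs became 57, without naive 4 70 and without naive 2 189; naive 2 had the highest naive levels of Tsc22d3 in astrocytes (576 CPM) and Sgk1 in oligodendrocytes (1619 CPM).

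Glucocorticoid responsive genes rose after odor in 8 of 19 members in astrocytes (15 adjusted over the list alone, median 0.49), 12 of 17 in oligodendrocytes (15, median 1.11), 4 of 13 in microglia (5, median 0.19) and 1 of 15 in neurons (10, median 0.66), called with an estimated correlation (highest adjusted p 0.0184). In endothelial and mural cells 0 of 15 and 0 of 7 rose (4 and 3 adjusted over the list alone; adjusted p = 0.161 and 0.193 with an estimated correlation). Immobilization and odor shared 44 raised and 13 lowered genes in astrocytes, where independent lists would share 0.498 and 0.0989, and simulated groups without effects 0.1 in all. Their fold changes had a covariance of 0.101 across genes, against 0.0411 in simulated unchanged groups with the same naive libraries (correlation 0.66 against 0.45; 0.14 and 0.13 with the naive libraries split). In oligodendrocytes they shared 29 raised genes (independent lists 0.271, simulated groups without effects 0.05 in all). The correlation of fold changes there was 0.58 against 0.47 in simulated unchanged groups with the same naive libraries, and 0.061 and 0.033 with the naive libraries split. Both comparisons used the same naive libraries, for which independent lists make no allowance. Groups simulated without effects have no true changes to share. The shared counts therefore cannot tell a common response from a deviation of the naive libraries. In immobilization over odor, the glucocorticoid list was called upward in astrocytes with the preset correlation (median 0.38, 1 of 19 members past the threshold, 10 adjusted over the list alone; adjusted p = 0.0781 with an estimated correlation), and Dio2 was higher by 1.18 (SE 0.16). Effectors in astrocytes had 2 of 18 members raised (adjusted p 0.0249 with an estimated correlation). Lost with an estimated correlation were heat shock genes, called upward in oligodendrocytes (median 0.36), endothelial cells (0.40), mural cells and precursors (0.33; adjusted p = 0.241, 0.185, 0.185 and 0.185). So were circadian genes in microglia and oligodendrocytes (adjusted p = 0.224), and synaptic genes in neurons and astrocytes (medians -0.09 and 0.19; adjusted p = 0.399 for both with an estimated correlation). The others were myelin genes in neurons (adjusted p = 0.303) and unfolded protein genes in precursors (median 0.30, adjusted p = 0.185).

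The last comparison asked how much the dissociation itself changed immediate early genes, over 3 Act-Seq and 2 conventional libraries with 1 library per treatment in the conventional arm. Microglia differed in 19 of 21 of these genes. Fos stood at 4747 and 3904 CPM in the saline and seizure conventional libraries against 7.06 to 13.3 CPM in the 3 Act-Seq libraries (log2 8.69, SE 0.27). Egr1 was higher by 8.46 (SE 0.28), Ier2 by 6.88 (SE 0.30) and Jun by 5.45 (SE 0.21). In oligodendrocytes Fos (7.13, SE 0.43), Fosb (7.44, SE 0.53) and Junb (6.88, SE 0.49) were higher. In precursors Fos (5.46, SE 0.28) and Fosb (6.36, SE 0.35) were higher, and in mural cells Fos (8.27, SE 0.82), Junb (7.28, SE 0.58) and Cebpb, an inflammatory transcription factor (4.74, SE 0.45). In endothelial cells Junb (4.54, SE 0.47) and Egr1 (4.33, SE 0.62) were higher, calls lost without seizure 2 (4.82 and 5.09, adjusted p 0.0521 for both), and that of Egr1 also without saline 7 (3.14, 0.174). Immediate early members were raised in 19 of 21 in microglia (median 4.15), 9 of 13 in oligodendrocytes, 8 of 11 in precursors, 10 of 14 in mural cells, and 6 of 19 in endothelial cells. They were raised in 1 of 16 in astrocytes and 1 of 17 in neurons, where 3 were lowered. Adjusted over the list alone these were 21, 10, 10, 13, 13, 1 and 1. Camera called the list upward in the first 5 classes with the preset correlation, and in none with an estimated one (microglia adjusted p = 0.338). All 15 inflammatory members tested in microglia were raised, among them Ccl3 (7.54, SE 0.34), Ccl2 (7.88, SE 0.41) and Tnf (5.99, SE 0.38; list median 4.11, adjusted p = 0.342 with an estimated correlation).

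**Figure D3:**
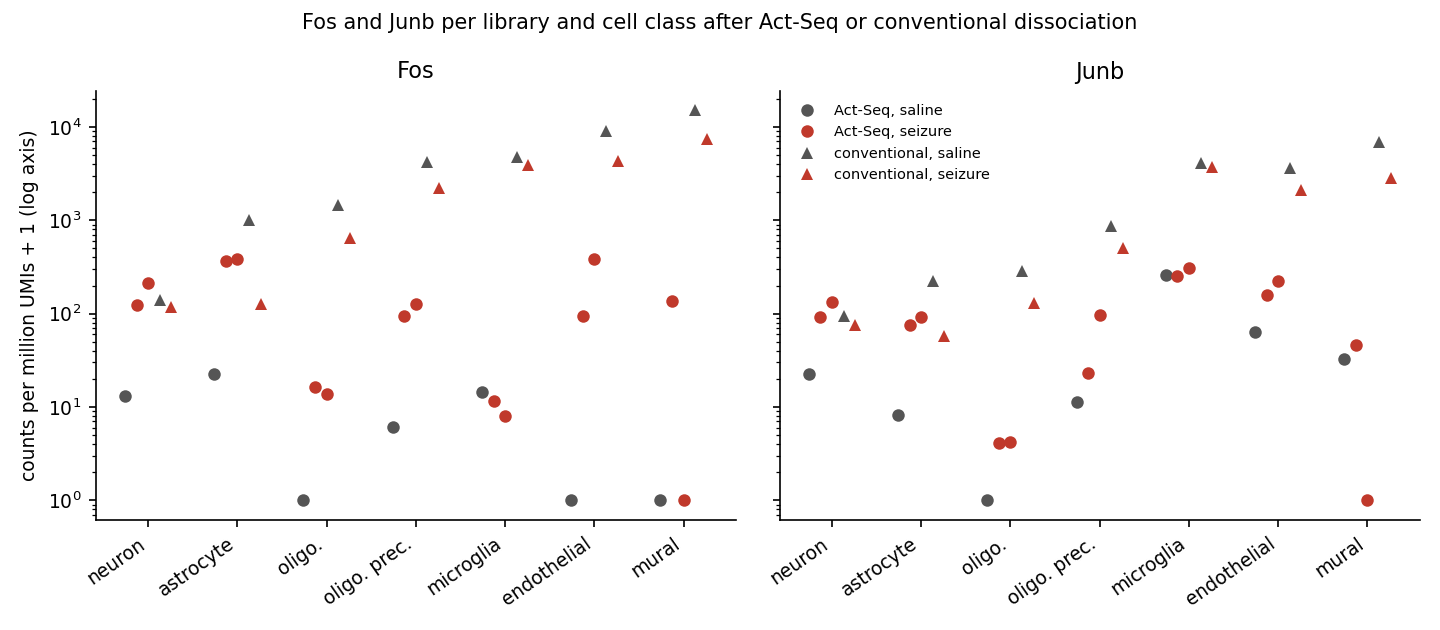
Fos and Junb in CPM plus 1 (log axis) in 7 cell classes of the saline Act-Seq, seizure Act-Seq (2), saline conventional and seizure conventional libraries; circles are Act-Seq, triangles conventional, gray saline and red seizure. Microglial Fos lay at 3904 and 4747 CPM in the conventional libraries and at 7.06 to 13.3 CPM in the Act-Seq libraries.

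The seizure effect differed between the methods in 32 class-gene pairs by the interaction term. Of its 4 arms, 3 hold 1 library, so the 1 residual degree of freedom comes from the 2 seizure Act-Seq libraries, and the others are assumed to vary like these. Astrocyte Fos stood at 21.5 CPM in saline and 361 and 388 CPM in seizure Act-Seq libraries, but at 1002 CPM in the saline and 126 CPM in the seizure conventional library (interaction -7.14, SE 0.38). Junb (-5.50, SE 0.51) and Egr1 (-6.33, SE 0.49) in astrocytes, Fos in oligodendrocytes (-7.07, SE 1.47) and Fos in neurons (-3.83, SE 0.58; adjusted p 0.0244) differed in the same direction. The additive values of astrocyte Fos (1.58, adjusted p 0.505) and Egr1 (0.83, 0.656) turned to -1.51 and -1.81 without saline 7 and to -1.50 and -1.80 without saline_conventional 1, all past the threshold. Without seizure_conventional 1 they were 5.62 and 4.50 (adjusted p 1.17e-11 and 3.53e-08), and without seizure 2 1.802 and 0.905, also past it. With 1 residual degree of freedom, no interaction could be tested with a library left out, and DESeq2 called 10 pairs.

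In all, with these genes among them, 4889 class-gene pairs differed between methods, 4300 of them in neurons, where the methods' cells fell into different clusters. Act-Seq neurons were mostly in the cluster led by Camk2a, Kif5a and Map2 (16.5%, 23.0% and 13.1% of cells in saline 7, seizure 1 and seizure 2, against 0.266% and 0.781% of conventional cells), and conventional neurons in clusters led by Meg3, Gal and Penk. Penk, the enkephalin precursor, was higher by 3.57 (SE 0.23) and Scg2 by 2.82 (SE 0.22) in conventional neurons, and the astrocyte genes Mlc1 (-6.60, SE 0.32) and S100b (-6.13, SE 0.31) were lower, S100b from between 1122 and 1403 CPM to 17.2 and 24.9 CPM. An unnamed cluster led by Kif5a with astrocyte genes took 19.2%, 18.6% and 17.2% of Act-Seq cells and 0.585% and 1.87% of conventional cells; all unnamed cells together were 21.3%, 20.2% and 18.5% against 1.54% and 3.20%. Microglia too fell into a cluster led by P2ry12 in Act-Seq libraries (9.55%, 8.16% and 9.44% against 0.213% and 1.41%) and one led by Ccl4 and Ccl3 in conventional ones (9.36% and 8.74% against 0.0498%, 0.281% and 0.623%). In newly formed oligodendrocytes edgeR called 0 genes (unadjusted 74, DESeq2 0). Lists that moved with the method in other ways, called with the preset correlation alone, were glucocorticoid responsive genes up in astrocytes (6 of 18 raised, adjusted p = 0.52 with an estimated correlation). They moved down in neurons (9 of 15 lowered), as neuropeptides moved up there (14 of 16; adjusted p = 0.344 for both with an estimated correlation).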

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

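The tests on cluster N12, on single odor libraries, on age, on the time of day and on Arc in 2 sets of glial and vascular classes were chosen after the results were seen; the other tests were planned.

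For normally distributed values, which levels near 0 CPM are not, chance sets 1 library apart in about 1 in 20 groups. In 12 of 103 groups of values searched, 1 library stood far from the rest of its group. In naive libraries these were the mural share of naive 6 (6.97674% of its 43 cells, others 1.54% to 2.40%), Avp in neurons of naive 4 (25438.9 CPM, others 0 to 2979), Snhg11 in neurons of naive 5 (6814.6 CPM, others 482 to 2209) and Tsc22d3 in astrocytes of naive 2 (576.049 CPM, others 213 to 313). Sgk1 in oligodendrocytes of naive 2 (1619.46 CPM, others 111 to 203) and Cdkn1a in oligodendrocytes of naive 4 (22.6806 CPM, others 0 to 2.93) also stood apart. In immobilization libraries these were the endothelial share of immobilization 4 (10.4396%, others 4.11% to 4.60%), its neuronal Sst (433.018 CPM, others 96.6 to 119) and Fos in microglia of immobilization 3 (5.59234 CPM from 1 UMI, others 0). In odor libraries these were the total of odor 4 (533034 UMIs, others 2526530 to 2886720), its precursor share (9.88235%, others 2.05% to 3.29%) and Apold1 in endothelial cells of odor 2 (115.685 CPM, others 191 to 204).

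The seizure effect differed between the dissociation methods, by the interaction term, in 32 class-gene pairs. Conventional minus Act-Seq, it was -7.136 for Fos, -5.495 for Junb and -6.326 for Egr1 in astrocytes, -4.395 for Nr4a1 in microglia, -5.081 for Jun and -6.56 for Nr4a1 in mural cells, -3.827 for Fos in neurons and -7.067 for Fos in oligodendrocytes. Other genes went the opposite way: Cxcl10 in astrocytes (9.521), Dbp in microglia (4.282), and Hes1 (4.991) and Apoe (3.814) in mural cells. The conventional arm had 1 library per treatment and the saline Act-Seq arm 1 library, so a library and its treatment cannot be told apart there.

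Immediate early genes rose outside neurons after seizure, and RNA of activated neurons in other droplets is a candidate explanation, which would bring Arc and Fos in the neuronal ratio. In neurons of the seizure libraries Arc made up 38.5% of Arc plus Fos UMIs (exact 95% interval 33.1 to 44.0), but in astrocytes 3.5168% (2.24 to 5.23) and in the other classes together 14.7651% (9.49 to 21.5), which argues against it as the whole source. In endothelial, mural and precursor cells the value was 0.9009% (1 of 111 UMIs), which argues against it there. In microglia and oligodendrocytes together it was 55.2632% (38.3 to 71.4). In oligodendrocytes alone it was 66.6667% (46.04 to 83.48, 18 Arc and 9 Fos UMIs), above the neuronal interval. Arc was not raised there after seizure (26.2 CPM, n = 2, against 47.3 CPM in naive libraries, n = 5). The ratio therefore cannot trace Fos in oligodendrocytes. In microglia alone the value was 27.2727% (6.02 to 60.97, 3 Arc and 8 Fos UMIs), too wide to decide. RNA of neurons as the source of the 17 Fos UMIs of those 2 classes stays open. A response of the astrocytes, vessels and precursors themselves stays a hypothesis.

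The 10 genes lowered in odor neurons, Meg3, Snhg11 and Avp among them, had a median log2 of -2.29 (median SE 0.43). Without the cells of N12 the median was -1.011 (SE 0.39, 9 genes, 1 past the threshold), so a lower share of N12 (exact permutation p = 0.339) may account for much of it. Whether it accounts for all stays open, since the genes were chosen for being low. Snhg11 stood at 0.039 within the Meg3-led or Snhg11-led clusters and at -0.922 (adjusted p 0.713) with own clusters as classes. Without odor 3 the median was -2.1187 (SE 0.50) with 0 of the 10 past the threshold in edgeR. The calls thus need that library (4 were past the threshold without odor 1 and 6 without odor 2). The other odor libraries were low too, but the genes were chosen with these included. The median therefore cannot exclude odor 3 as the main source. With age as a covariate the median was -2.5732 (SE 0.49, 6 of 10 past the threshold). This goes against age as the whole cause, with the same limit from the choice of genes. Chance could not be excluded for the 11 neuronal genes: 8 of 56 splits gave as many, and 1 of them, which set naive 1, 4 and 5 apart, gave 40, several times the real count, which points to a structure among the naive libraries. A biological effect of odor stays open.

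Glucocorticoid responsive genes were raised after odor as well as after immobilization. If a different time of day were the cause, clock genes would move too; their median in odor astrocytes was 0.161 (SE 0.12, 7 genes), against a bound of 0.244 set from the median of the glucocorticoid genes, and the spread keeps this open. If the naive libraries were low for another reason, the saline library would lie above them; it lay above all naive libraries in 1 of 6 classes, microglia, so neither reading can be told apart, since there is 1 saline library. Of 100 splits, 2 gave as many as the 115 class-gene pairs outside neurons, the real split among them. The highest other, 167, came from a split that differs by naive 2 alone. This argues against chance as the source of the 115 pairs without excluding it. For the 18 list calls chance stays open (7 of 100, highest 27). The stress of exposure, an odor response and a difference between batches stay open, as untested.

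After immobilization, 1 of 100 splits, the real one, gave as many as the 391 pairs outside neurons. The highest other, 309, came from a split that differs by naive 2 alone. This argues against chance for these pairs without excluding it. Chance stays open for the 7 neuronal genes (14 of 100, highest 24) and the 21 list calls (11 of 100, highest 26). For the 0 immediate early genes in neurons after immobilization and odor, 100 of 100 and 56 of 56 splits in edgeR gave as many, with 0 the highest, so these splits say nothing.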

How the results depend on the processing

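Removal of the 5% of cells with the highest doublet scores, libraries under 300 cells, other cells taken as neurons, neurons or Kif5a-led clusters left out, and the contrast of immobilization against odor were chosen after the data were seen. Over 9029 tests of named genes under the alternatives, 8138 kept their direction and side of the threshold, 608 lost the threshold and 154 gained it. A further 119 changed sign with neither value past the threshold, and 10 turned with a value past it. Of 4222 with 1 library left out, 348 lost it and 61 gained it; of 555 by DESeq2, 103 and 6; of 555 by RLE scaling, 4 and 4; of 419 with age as a covariate, 25 and 5. For each value below that moved, the cause was not tested unless fewer genes, cells or libraries were used.

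With an estimated correlation the list calls were 13 after immobilization, 6 after odor, 11 for seizure against immobilization and 3 for immobilization against odor. DESeq2 called 4 neuronal genes after immobilization, 1 after odor and 3 for seizure against immobilization, and 3023 pairs between dissociations and 10 for the interaction. With no filter on low counts the neuronal counts were 21 after seizure, 22 after immobilization, 55 after odor and 14 for seizure against immobilization, the pairs outside neurons 191 after seizure and 234 after odor, and the interaction 71. RLE scaling gave 54 interaction pairs. With age as a covariate 6 neuronal genes changed after seizure, 5 after immobilization and 8 after odor, and Sst (0.881) and Npy (0.832) after seizure lost their calls (adjusted p 1 for both).

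With own clusters as classes, 15 neuronal genes changed after seizure (8 immediate early), 12 after immobilization (1), 6 after odor (1) and 12 for seizure against immobilization. With all cells of the authors' neuron class the counts were 19 (10 immediate early) after seizure, 22 (2) after immobilization, 1 immediate early gene after odor and 11 for seizure against immobilization. With neuron-like clusters led by Meg3 or Snhg11 as neurons, which hold 11458 to 154505 UMIs per library and 2072 tested genes, they were 2 (0 immediate early by edgeR) after seizure, 1 after immobilization, 3 after odor and 3 for seizure against immobilization. Without N12 there were 2 odor genes, without libraries under 300 cells 3, and without the 5% of highest doublet scores 7; the latter gave 70 interaction pairs. Between dissociations 1101 pairs differed without the Kif5a-led clusters and 589 without neurons.

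Leaving out 1 library moved the neuronal odor count from 1 (odor 3) to 28 (naive 3), with 5 without naive 1 or odor 1, 7 without naive 5 or odor 2, 20 without naive 2 and 19 without naive 4. The pairs outside neurons went from 57 (odor 3) to 189 (naive 2) after odor, with 70 without naive 4, from 64 (seizure 2) to 133 after seizure, and from 248 (immobilization 2 or 3) to 433 after immobilization. Seizure against immobilization gave 3 (immobilization 1 or 2) to 9 neuronal genes. The Fos share difference after seizure ran from 7.3854 (seizure 1) to 8.3437 points (seizure 2), where the exact permutation p is 0.143, the smallest left, and was 7.6286 without libraries under 300 cells (exact permutation p = 0.0667). That after immobilization ran from -0.204 to 0.1481 points (above 0 without naive 1, 2 or 4 or immobilization 3 or 4), and was 3.1715 without thinning (exact permutation p = 0.0476). The inhibitory minus excitatory difference after seizure ran from -0.2513 (seizure 2) to 0.3708, with -0.2097 without naive 2.

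The genes that turned with a value past the threshold were Snhg11 in neurons after odor (0.039 in the Meg3-led or Snhg11-led clusters) and Sst and Npy in neurons after seizure (-0.026 and -0.278 without N12; Npy -0.152 without seizure 1 to 2.217). Between dissociations astrocyte Fos ran from -1.506 (saline 7) to 5.618 (seizure_conventional 1), astrocyte Egr1 from -1.811 (saline 7) to 4.503 and neuronal Jun from -1.133 (saline 7) to 1.588; without saline_conventional 1 these were -1.496, -1.801 and -1.088.

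Same-numbered libraries had mean correlations of 0.00135 to 0.0202 in their deviations, so the numbers do not pair them; with the replicate number as a block the neuronal counts were 11 after seizure, 6 after immobilization, 16 after odor and 7 for seizure against immobilization. An interaction with 1 library left out has no residual degrees of freedom and was not run. Depth limits the mural cells (1020 genes tested) and the endothelial cells (3968) most, against 10520 in astrocytes.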

Other observations

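The class of neuron-class cells outside the neuron table and the match of cells between tables were chosen after the data were seen; the saline test was planned.

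The cells that the authors' neuron class holds outside the neuron table formed a class of their own, with 8619 genes tested. After seizure 6 of 12 immediate early members rose there, and 8 adjusted over the list alone (median log2 2.22, adjusted p 1.26e-05 with an estimated correlation), among 10 changed genes. After immobilization 7 genes changed and 0 of 12 immediate early members did (3 adjusted over the list alone, median 0.54; unadjusted 380 and DESeq2 3 over all genes by edgeR's test), while glucocorticoid responsive genes rose in 3 of 16 (13 adjusted over the list alone, median 0.83). After odor 5 genes changed, and 1 of 16 glucocorticoid responsive genes rose (12 adjusted over the list alone, median 0.58).

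Saline injection itself was tested as a hypothesis for raised glucocorticoid responsive genes. The saline Act-Seq library lay above all naive libraries in 1 of 6 classes: at 5.86 against at most 5.81 in microglia, but at 6.41 in astrocytes and 5.84 in oligodendrocytes against up to 6.49 and 6.20 in naive libraries (mean log2 of CPM plus 10). It lay above the naive mean in all 6 classes, such as 6.41 against 6.08 in astrocytes and 5.84 against 5.53 in oligodendrocytes. The planned bound, the range of the naive libraries, could not exclude a rise smaller than their spread, so with 1 library the hypothesis stays open.

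All 1777 cells of seizure 1 and 1123 cells of seizure 2 in the dissociation table had the same counts as 1 cell of that library in the table of all cells, over the genes in both, and 0 of them carried the same barcode, although 662 and 297 barcodes are named in both tables. Cells were therefore not matched by barcode between those tables.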
